A study of Homo sapiens with 9 samples.

How the data were processed

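The series held 9 libraries of total RNA from a reconstructed human oral mucosa, a layered culture of normal oral keratinocytes over fibroblasts kept in serum-free medium. Tissues were exposed to everolimus at 0, 32 or 64 ng/mL for 60 hours, with 3 libraries per concentration. Per the labels' protocols, RNA was extracted on silica columns and 250 ng of each sample entered a stranded, poly(A)-selecting library kit. Per the submitters' processing notes, the upstream work used the GRCh38 build, Bowtie2 2.1.0 and RSEM 1.2.15. The annotation and the counting options are not given in the sources used here.

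The authors deposited a table of expected counts per gene, as RSEM estimates them, which divides a read that fits several genes among those genes, so values need not be whole. They also deposited a table of CPM for the same genes and libraries. The 9 single-library files held the same expected counts as the table of the whole series. The table listed 25343 genes by symbol, of which 19496 had a count in some library. None of the 13 mitochondrial-encoded genes looked for was in it. Of the genes tested, 4787 (34.3%) had a fractional expected count in some library (more than 0.001 from a whole number), so their reads were shared with another gene and their levels are less certain. Poly(A) selection leaves out most RNA without a tail, rounding moves only the lowest counts, and TMM takes most genes as unchanged, so a shift of total RNA per cell would not be seen.

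Libraries were grouped by the title and the concentration field. For the 3 libraries titled 64 ng/mL the free-text treatment field gives 32 ng/mL, so the labels conflict there. Nothing in the labels says that replicates came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries was a duplicate: within groups, chi-square per degree of freedom of the counts ran from 1.72 to 16.4. Library totals ran from 11819947 to 23018377 expected counts.

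Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 13938 genes. Libraries were scaled by TMM, and glmQLFit and glmQLFTest were run on all 9 libraries together with 1 mean per group, no covariate and 6 residual degrees of freedom. The contrasts were 32 against 0, 64 against 0, 64 against 32, and the mean of 32 and 64 against 0. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold limit. The common biological coefficient of variation was 7.42%. Levels are given as CPM with TMM-scaled library sizes, as mean ± SD of 3 libraries. Log2 fold changes are those of the edgeR fit, as estimate ± SE. The test itself gives no SE, so the absolute log2 fold change divided by the square root of the F statistic was used.

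Lists of genes were fixed from general knowledge: 31 lists of 742 genes, 8 of them in more than 1 list, covering pathways, keratinocyte states and markers of other cell types. The 27 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Members were also counted with the adjustment made over each list alone.

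The rule for named genes took, for each concentration against untreated, the 10 genes each way with the largest log2 fold change among called genes with a mean CPM of 5 or more and no overlap between the groups' libraries, and 5 each way for 64 against 32. From each list it took up to 4 called members with the largest change against untreated, or the most abundant member where none was called. MTOR and FKBP1A were added in every comparison. These lists, the rule, the tests and most of the alternative analyses were fixed before the data were examined. Genes used to infer sex were left out of the tables (17 genes). The values of 1 gene taken by the rule are not reported here. Gene positions come from GENCODE release 29 on GRCh38, matched by symbol for 13051 of the 13921 tested genes that the tables list.

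The alternative analyses fixed in advance were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, counts not rounded, the authors' CPM on the scale of log2(CPM + 1) with limma-trend, the replicate number as a block, only the groups compared in the fit, a stricter adjusted p of 0.01, a fold limit of 2, and each library left out in turn. After the data were seen, thinning every library to the smallest total and a fit without the 64 ng/mL library 3 and the 32 ng/mL library 2 were added.

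The scripts were tested on simulated data: negative binomial counts drawn from the untreated tissue's gene proportions, each library's total and the fitted spread, with 200 genes changed in each of 3 sets per comparison. For 32 against 0, 19.5%, 62.8%, 89.3% and 95.3% of genes changed by 1.25, 1.5, 2 and 4 times were recovered, and 7.05% of calls were false. For 64 against 0 the shares were 20.7%, 63.7%, 86.6% and 96.6%, with 5.66% false. For 64 against 32 they were 26.7%, 57.5%, 86.6% and 98.6%, with 7.68% false. For the mean of both concentrations they were 35.6%, 70.5%, 91.9% and 100%, with 6.39% false. A simulated list raised by 1.25 times was called in 9 of 9 trials and an unchanged list in 0 of 9, at an unadjusted camera p under 0.05. Genes were drawn independently there, while the tested lists had estimated correlations of up to 0.53 (ATF4 and amino acid supply). The trials therefore do not measure how often lists were falsely called in these data. Figures were drawn with matplotlib 3.10.9.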

Results

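RNA from a reconstructed human oral mucosa was measured by RNA-seq after 60 hours with everolimus, a drug that binds FKBP1A and through it inhibits the kinase MTOR, and for which stomatitis is a frequent side effect. There were 3 untreated libraries, 3 at 32 ng/mL and 3 at 64 ng/mL. The untreated libraries 1, 2 and 3 held 21601138, 23018377 and 15253405 expected counts. Those at 32 ng/mL held 19969947, 18568718 and 14956227, and those at 64 ng/mL held 14511838, 12119454 and 11819947. The 10 most abundant genes took 17.3% to 17.7% of counts in untreated tissue, 16.3% to 17.4% at 32 ng/mL and 14.97% to 15.8% at 64 ng/mL.

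The groups separated on the first principal component of log2 CPM, which held 34.5% of the variance. Untreated libraries lay between -22.0 and -20.4, those at 32 ng/mL between -8.25 and -5.13, and those at 64 ng/mL between 23.3 and 32.8. On the second component (18.5% of variance) the 64 ng/mL library 3 lay at -7.15, against 15.6 and 11.1 for the others of its group. The 32 ng/mL libraries lay between -23.5 and -14.4 there, and the untreated ones between 12.3 and 13.3. On the third (14.3% of variance) the 64 ng/mL library 3 stood apart from the others of its group, at -29.2 against 16.0 and 12.2. Its counts differed from theirs with a chi-square per degree of freedom of 16.4 and 12.5, against 2.65 between those 2 libraries. At 32 ng/mL, library 2 differed most, with 8.71 and 4.82 against 2.45. Among untreated libraries the values were 1.72 to 2.63.

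**Figure D1:**
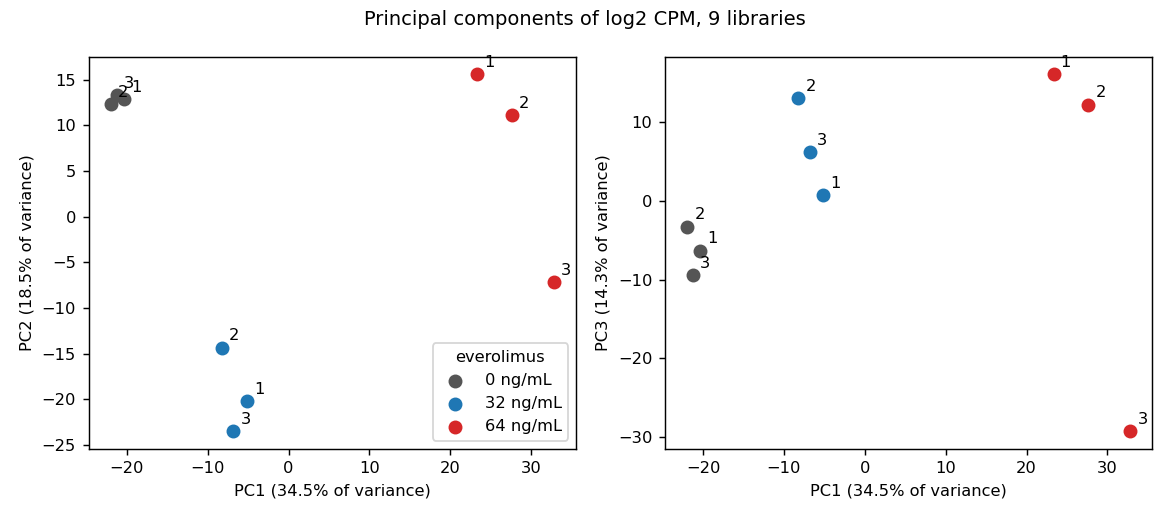
Principal components of log2 CPM over the 9 libraries, with component 1 on the horizontal axes (34.5% of variance) and components 2 (18.5%) and 3 (14.3%) on the vertical axes. Each point is 1 library, coloured by everolimus concentration and marked with its replicate number; the 64 ng/mL library 3 lies at -29.2 on component 3, apart from the others of its group at 16.0 and 12.2.

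The drug's target and its binding protein were first examined. MTOR (chromosome 1, 11106535 to 11262507, minus strand, GRCh38) was at 75.6 ± 1.73 CPM in untreated tissue and 78.6 ± 3.47 at 32 ng/mL (SD, n = 3), a log2 change of 0.06 ± 0.06 (SE) that did not pass the test (edgeR adjusted p = 0.65). At 64 ng/mL it rose to 95.9 ± 2.80 CPM, by 0.34 ± 0.06 (adjusted p = 8.0e-04). FKBP1A (chromosome 20, 1368978 to 1393172, minus strand) was at 227 ± 6.52 CPM untreated and 219.7 ± 1.32 at 32 ng/mL (log2 change -0.05, adjusted p = 0.67), and fell to 152 ± 4.52 CPM at 64 ng/mL, by 0.58 ± 0.05 on the log2 scale (adjusted p = 3.1e-06). FKBP1A had fractional counts in 8 libraries.

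The first comparison asked what the lower concentration did. At 32 ng/mL, the lists of the outermost, cornified layer of the epithelium and of the suprabasal layers beneath it had the largest median rises. In them 22 of 35 and 20 of 25 genes rose. Both camera calls were lost with an estimated correlation (adjusted p = 0.0673 for each). LOR, which encodes the cornified envelope protein loricrin (chromosome 1, 153259700 to 153262122, plus strand), went from 20.4 ± 0.543 to 134 ± 11.6 CPM, a 6.56-fold rise (log2 2.71 ± 0.08, edgeR adjusted p = 6.4e-11). ARG1, an arginase of the urea cycle (chromosome 6, 131573144 to 131584332, plus strand), went from 1.98 ± 0.184 to 15.1 ± 0.311 CPM, 7.66-fold (log2 2.94 ± 0.16, adjusted p = 1.4e-08). SCD, the stearoyl-CoA desaturase of lipid synthesis (chromosome 10, 100347124 to 100364834, plus strand), fell from 2785 ± 20.9 to 1325 ± 19.8 CPM (log2 -1.07 ± 0.06, adjusted p = 1.2e-08). In all, 1346 of 13938 genes were called, 788 up (58.5%) and 558 down, of which 121 and 58 changed at least 2-fold. With upper-quartile scaling the split was 652 up (47.9%) and 708 down. Groups did not overlap in 1343 of the called genes and in 33.1% of all genes tested, where chance gives 10%.

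In the cornified envelope list, 22 of 35 genes rose and 4 fell (24 and 4 adjusted over the list alone), with a median log2 change of 0.64 (camera adjusted p = 1.9e-16; adjusted p = 0.0673 with an estimated correlation). LOR, the protease gene ASPRV1 (16.3 ± 0.822 to 92.0 ± 7.21 CPM, 5.64-fold) and LCE1C of the late cornified envelope family (4.41 ± 0.756 to 29.8 ± 2.43 CPM, log2 2.74 ± 0.12) were among them. In the oral suprabasal differentiation list, 20 of 25 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.76 (adjusted p = 4.3e-20; adjusted p = 0.0673 with an estimated correlation). KRT13 and KRT4, the keratin pair of non-cornifying oral epithelium, rose by 1.07 ± 0.06 and 1.17 ± 0.09, and CRCT1 rose by 1.32 ± 0.08. The 10 genes with the largest rise were C1orf68, ARG1, LCE1B, LCE2B, LCE1C, LOR, LCE2C, LCE1E, LCE1F and ASPRV1, by 2.48 to 3.75. The LCE genes other than LCE1F had fractional counts in 6 or more libraries, as did KRT13 and KRT4. In the basal keratinocytes list, 7 of 18 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.10, adjusted p = 0.0039; adjusted p = 0.154 with an estimated correlation). KRT14 fell by 0.35 ± 0.06 and the hemidesmosome collagen COL17A1 by 0.32 ± 0.05. The count of 7 was 3, 4 and 3 without untreated library 1, 2 and 3, and 4 and 3 without the 32 ng/mL library 1 and 3.

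Cytosolic ribosomal protein genes rose by small amounts: 46 of 77 rose and 0 fell (71 and 0 adjusted over the list alone), with a median log2 change of 0.24 (adjusted p = 1.8e-23; adjusted p = 0.16 with an estimated correlation). RPL41 rose by 0.32 ± 0.06 (adjusted p = 0.0047). The count of 46 was 16, 27 and 18 without untreated library 1, 2 and 3, 24 and 20 without the 32 ng/mL library 2 and 3, 73 without the 64 ng/mL library 3, and 30 with upper-quartile scaling. In the inflammatory cytokines list, 12 of 26 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.35, adjusted p = 2.4e-07; adjusted p = 0.0673 with an estimated correlation), and 7 rose without the 32 ng/mL library 3. The neutrophil chemokine CXCL5 went from 31.9 ± 0.826 to 75.7 ± 2.97 CPM, 2.38-fold, and the granulocyte growth factor CSF3 rose by 1.38 ± 0.21. In the antimicrobial proteins list, 5 of 14 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.20, adjusted p = 0.0238; adjusted p = 0.45 with an estimated correlation). RNASE7 rose by 1.30 ± 0.12, and the defensin genes DEFB103A and DEFB103B, whose values were identical, by 1.22 ± 0.18. The call of this list was lost without untreated library 3 (adjusted p = 0.0505) and without the 32 ng/mL library 2 (0.123).

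The list of fibroblast matrix genes, fixed as markers of the other cell type in the tissue, moved with these groups. Which cell type expressed its members was not measured. In this list 11 of 29 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 1.6e-06, and adjusted p = 0.0673 with an estimated correlation). The count was 7 without any 1 of the untreated libraries. TAGLN, an actin-binding protein of contractile cells, rose by 0.96 ± 0.08, the fibroblast protease FAP by 0.90 ± 0.15 and FN1, which encodes fibronectin, by 0.71 ± 0.06. In the cell junctions list, 5 of 22 rose and 0 fell (8 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.0105; adjusted p = 0.154 with an estimated correlation). OCLN, a tight junction protein, rose by 0.49 ± 0.08. That count was 2, 1 and 2 without untreated library 1, 2 and 3, 2 without the 32 ng/mL library 1 or 3, 10 without the 64 ng/mL library 3, and 3 with upper-quartile scaling. In the FOXO targets list, 5 of 17 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.010; adjusted p = 0.206 with an estimated correlation). CITED2 rose by 0.64 ± 0.06 and the receptor gene ERBB3 by 0.31 ± 0.05.

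Several metabolic lists fell at 32 ng/mL. In the fatty acid synthesis list, 8 of 15 fell and 0 rose (9 and 0 adjusted over the list alone, median -0.27, adjusted p = 3.3e-08; adjusted p = 0.0673 with an estimated correlation). The desaturase FADS2 went from 53.3 ± 2.13 to 17.6 ± 1.63 CPM (log2 -1.59 ± 0.09) and SREBF1, the transcription factor of lipogenic genes, fell by 0.60 ± 0.07. In the cholesterol synthesis list, 3 of 25 fell and 0 rose (11 and 0 adjusted over the list alone, median -0.16, adjusted p = 0.00264; adjusted p = 0.0673 with an estimated correlation). In the glycolysis list, 8 of 21 fell and 0 rose (12 and 0 adjusted over the list alone, median -0.22, adjusted p = 1.0e-06; adjusted p = 0.171 with an estimated correlation). The glucose transporter SLC2A1 fell by 0.45 ± 0.06. In the NRF2 targets list, 8 of 18 fell and 2 rose (9 and 2 adjusted over the list alone, median -0.19, adjusted p = 0.00111; adjusted p = 0.0673 with an estimated correlation). The quinone reductase NQO1 fell by 0.82 ± 0.07, while the heme oxygenase HMOX1 rose by 1.02 ± 0.09. In the HIF1 targets list, 5 of 19 fell and 0 rose (7 and 2 adjusted over the list alone, median -0.12, adjusted p = 0.0466; adjusted p = 0.154 with an estimated correlation). NDRG1 fell by 0.48 ± 0.05. That call was lost without untreated library 2 (adjusted p = 0.0676), the 32 ng/mL library 2 (0.128) or library 3 (0.0763). With all libraries kept it was lost after thinning to the smallest total (0.0541) and with the replicate number as a block (0.0867). It was also lost without the 64 ng/mL library 3 and the 32 ng/mL library 2 together (0.180). The fatty acid synthesis count was 5 without untreated library 1 or 2 or the 32 ng/mL library 3. The cholesterol synthesis count was 5 without the 32 ng/mL library 2, 7 and 12 without the 64 ng/mL library 1 and 3, and 8 with upper-quartile scaling. The glycolysis count was 4 without untreated library 1 or the 32 ng/mL library 1 or 3 and 14 without the 64 ng/mL library 3, and the HIF1 targets count was 3 without untreated library 1 or 2.

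The 10 genes with the largest fall were G0S2, FADS2, PCDHGC5, NOS1, S100A7A, DYSF, SCD, APOE, ALOX15B and NRSN2, by -1.66 to -1.02. G0S2, an inhibitor of lipid droplet lipolysis, went from 25.6 ± 1.63 to 8.19 ± 1.53 CPM. The remaining 13 lists were not called at 32 ng/mL. The members that rose and fell were 2 and 7 of 29 for ATF4 and amino acid supply (2 and 7 adjusted over the list alone, camera adjusted p = 0.0742), among them DDIT4, a stress-induced inhibitor of mTOR signalling (-0.80 ± 0.08), and that list was called without the 64 ng/mL library 3 (adjusted p = 0.000815) or library 1 (0.0464), without the 64 ng/mL library 3 and the 32 ng/mL library 2 together (0.000726), and with limma-trend on the authors' CPM (0.0497). The 7 that fell were 3, 3 and 4 without untreated library 1, 2 and 3, 3 and 4 without the 32 ng/mL library 1 and 3, and 12 without the 64 ng/mL library 3. They were 0 and 0 of 20 for aminoacyl-tRNA synthetases (0 and 0 adjusted over the list alone, and 0 and 4 without the 64 ng/mL library 3), 2 and 0 of 30 for ribosome biogenesis (1 and 0), 0 and 1 of 48 for OXPHOS nuclear subunits (0 and 0, called without the 32 ng/mL library 2 at 0.0349 and without that library and the 64 ng/mL library 3 at 0.0143), 0 and 2 of 20 for p53 targets (1 and 4) and 4 and 5 of 36 for lysosome and autophagy (4 and 7). They were 0 and 2 of 10 for the pentose phosphate pathway (0 and 2), 1 and 2 of 7 for simple epithelium (1 and 2), 5 and 2 of 13 for stress keratins and alarmins (5 and 3), 5 and 3 of 19 for wound repair and proteases (5 and 3), 3 and 1 of 31 for the interferon response (3 and 3), 2 and 2 of 26 for mTOR pathway components (2 and 2) and 1 and 2 of 40 for proliferation (1 and 2). Adjusted p of these 12 lists ran from 0.336 to 0.804, and the counts are unsteady: over the alternatives those that fell ran from 0 to 9 for OXPHOS nuclear subunits, 2 to 9 for lysosome and autophagy, 0 to 4 for p53 targets and 1 to 5 for the interferon response. They ran from 2 to 6 for stress keratins and alarmins and 2 to 5 for mTOR pathway components. Without the 64 ng/mL library 3, 5 rose and 1 fell for ribosome biogenesis. The same fit gave 6 and 4 for stress keratins and alarmins and 3 and 4 for mTOR pathway components. For simple epithelium the median (-0.05) and the mean (0.04) differed in sign. At 32 ng/mL no list was called by camera with an estimated correlation (0 of 27, with 8 at an unadjusted p under 0.05), and fry called 14.

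The number of genes called at 32 ng/mL moved with single libraries. It was 723, 752 and 795 without untreated library 1, 2 and 3, 893 and 774 without the 32 ng/mL library 1 and 3, and 2371 without the 64 ng/mL library 3, which enters through the shared estimate of spread. It was 2345 with only the groups compared in the fit, and 3227 without the 64 ng/mL library 3 and the 32 ng/mL library 2.

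The second comparison asked what the higher concentration did. At 64 ng/mL the 10 largest rises included the keratins KRT76 and KRT4 and the matrix and contractile genes FN1 and TAGLN, and genes of the cell cycle and of sterol synthesis fell. KRT76, a keratin of the oral epithelium (chromosome 12, 52768155 to 52777345, minus strand), went from 9.68 ± 0.330 to 50.1 ± 6.67 CPM, 5.19-fold (log2 2.38 ± 0.10, edgeR adjusted p = 1.8e-09). FN1 (chromosome 2, 215360440 to 215436172, minus strand) went from 1103 ± 7.08 to 4563 ± 433 CPM, 4.14-fold (log2 2.05 ± 0.07, adjusted p = 7.2e-11). FADS2 (chromosome 11, 61792980 to 61867354, plus strand) went from 53.3 ± 2.13 to 11.3 ± 1.202 CPM (log2 -2.23 ± 0.10, adjusted p = 1.8e-09). In all, 3928 genes were called, 2035 up and 1893 down, of which 176 and 280 changed at least 2-fold. With upper-quartile scaling the split was 1752 up (44.96%) and 2145 down. Groups did not overlap in 3851 of the called genes and in 42.5% of all genes tested, where chance gives 10%. No left-out library moved this count by more than 1.5 times.

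In the cholesterol synthesis list, 21 of 25 fell and 0 rose (21 and 0 adjusted over the list alone, median -0.60, adjusted p = 5.9e-12), and the call held with an estimated correlation (adjusted p = 0.00784). The sterol oxidase gene MSMO1 went from 324 ± 22.7 to 131 ± 20.6 CPM (log2 -1.30 ± 0.13), and STARD4, a sterol carrier, fell by 1.22 ± 0.15. In the fatty acid synthesis list, 12 of 15 fell and 0 rose (13 and 0 adjusted over the list alone, median -0.54, adjusted p = 1.2e-08, and adjusted p = 0.0295 with an estimated correlation). SCD was at 769 ± 52.7 CPM (log2 -1.86 ± 0.06). In the proliferation list, 23 of 40 fell and 1 rose (26 and 1 adjusted over the list alone, median -0.77, adjusted p = 7.5e-10, and adjusted p = 0.0295 with an estimated correlation). The survivin gene BIRC5 went from 3.90 ± 0.690 to 1.18 ± 0.199 CPM (log2 -1.69 ± 0.22) and the mitotic kinesin KIF2C fell by 1.78 ± 0.37. In the HIF1 targets list, 14 of 19 fell and 1 rose (14 and 1 adjusted over the list alone, median -0.44, adjusted p = 4.0e-08, and adjusted p = 0.0105 with an estimated correlation). The carbonic anhydrase CA9 went from 7.63 ± 1.09 to 1.90 ± 0.778 CPM (log2 -1.98 ± 0.26), and the oxygen-sensing hydroxylase EGLN3 fell by 1.49 ± 0.08. In the glycolysis list, 18 of 21 fell and 0 rose (18 and 0 adjusted over the list alone, median -0.58, adjusted p = 4.1e-13; adjusted p = 0.0896 with an estimated correlation). The aldolase ALDOC went from 34.2 ± 1.26 to 10.7 ± 0.828 CPM (log2 -1.68 ± 0.09), and SLC2A1 fell by 1.19 ± 0.06.

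Amino acid genes fell as well. In the ATF4 and amino acid supply list, 17 of 29 fell and 0 rose (20 and 0 adjusted over the list alone, median -0.41, adjusted p = 6.5e-06; adjusted p = 0.424 with an estimated correlation). DDIT4 went from 210.0 ± 5.83 to 73.0 ± 8.39 CPM (log2 -1.52 ± 0.08), and the mitochondrial folate enzyme ALDH1L2 fell by 1.28 ± 0.12. In the 64 ng/mL library 3 this list lay 0.42 log2 units below the others of its group (median difference -0.42, above them in 2 of 29 genes). In the aminoacyl-tRNA synthetases list, 13 of 20 fell and 2 rose (14 and 2 adjusted over the list alone, median -0.26, adjusted p = 4.0e-04; adjusted p = 0.185 with an estimated correlation). GARS fell by 0.63 ± 0.07 and QARS rose by 0.64 ± 0.06. In the NRF2 targets list, 10 of 18 fell and 2 rose (10 and 3 adjusted over the list alone, median -0.27, adjusted p = 5.4e-04; adjusted p = 0.0566 with an estimated correlation). The peroxidase GPX2 went from 26.1 ± 2.08 to 9.47 ± 0.928 CPM. The 10 genes with the largest fall were CKMT1B, FADS2, SPRR4, NDUFA4L2, PGF, PCDHGC5, PLTP, ALOX15B, ARTN and SCD, by -2.40 to -1.86. CKMT1B, a mitochondrial creatine kinase with a near-identical copy, had fractional counts in all 9 libraries. NDUFA4L2, a hypoxia-induced mitochondrial protein, went from 214 ± 7.502 to 50.7 ± 8.88 CPM.

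Cytosolic ribosomal protein genes were again higher, with 63 of 77 up and 0 down (70 and 0 adjusted over the list alone, median 0.32, adjusted p = 9.5e-19; adjusted p = 0.246 with an estimated correlation). RPL41 rose by 0.66 ± 0.06. In the fibroblast matrix list, 11 of 29 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.13, adjusted p = 0.00206; adjusted p = 0.184 with an estimated correlation). TAGLN went from 17.0 ± 0.747 to 71.7 ± 4.43 CPM (log2 2.08 ± 0.08) and the matrix protein MXRA5 rose by 1.42 ± 0.10, while COL1A1, an abundant fibroblast collagen named after its values were seen, had a log2 change of 0.01 (adjusted p = 0.931). In the cell junctions list, 11 of 22 rose and 4 fell (12 and 4 adjusted over the list alone, median 0.18, adjusted p = 0.0122; adjusted p = 0.184 with an estimated correlation). The desmosomal DSP went from 6771 ± 113 to 10121 ± 843 CPM. In the FOXO targets list, 9 of 17 rose and 1 fell (9 and 2 adjusted over the list alone, median 0.27, adjusted p = 0.0142; adjusted p = 0.278 with an estimated correlation). The insulin receptor INSR rose by 0.95 ± 0.08 and its substrate IRS2 by 0.72 ± 0.10. That call was lost without the 64 ng/mL library 3 and the 32 ng/mL library 2 together (adjusted p = 0.0665).

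In the oral suprabasal differentiation list, 11 of 25 rose and 4 fell at 64 ng/mL (12 and 5 adjusted over the list alone, median 0.12, adjusted p = 0.0311; adjusted p = 0.543 with an estimated correlation). KRT4 went from 2129 ± 34.3 to 8680 ± 1436 CPM (log2 2.03 ± 0.09) and KRT13 from 6364 ± 54.4 to 16094 ± 860 CPM (log2 1.34 ± 0.06). The call was lost without the 64 ng/mL library 3 (adjusted p = 0.273, with 7 genes down), in which this list lay 0.31 above the others of the group (22 of 25 genes). The cornified envelope list was not called: 13 of 35 rose and 11 fell (15 and 11 adjusted over the list alone, median 0.01, adjusted p = 0.505), with LOR still up by 1.15 ± 0.08, and it lay 0.17 above the others in the same library (25 of 35 genes). ARG1 was at 3.16 ± 0.923 CPM (log2 0.66 ± 0.20, adjusted p = 0.024), a call lost without untreated library 1 (adjusted p = 0.0598), untreated library 2 (0.0880) or the 64 ng/mL library 3 (0.129), and with only the groups compared in the fit (0.0639). The 10 genes with the largest rise were KRT76, FMO2, TAGLN, FN1, KRT4, IL23A, COL22A1, DUOX2, NPL and NEB, by 1.76 to 2.38.

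The other 13 lists were not called at 64 ng/mL, with adjusted p from 0.0926 to 0.748. The members that rose and fell were 1 and 7 of 48 for OXPHOS nuclear subunits (1 and 7 adjusted over the list alone), 3 and 9 of 18 for basal keratinocytes (3 and 9), 3 and 1 of 7 for simple epithelium (3 and 1), 2 and 6 of 20 for p53 targets (2 and 6) and 9 and 5 of 26 for mTOR pathway components (11 and 5). They were 6 and 11 of 36 for lysosome and autophagy (7 and 14), 8 and 5 of 26 for inflammatory cytokines (9 and 5), 5 and 6 of 19 for wound repair and proteases (7 and 6), 1 and 5 of 10 for the pentose phosphate pathway (1 and 5) and 6 and 4 of 31 for the interferon response (6 and 4). They were 3 and 3 of 30 for ribosome biogenesis (3 and 2), 2 and 4 of 14 for antimicrobial proteins (2 and 5) and 6 and 5 of 13 for stress keratins and alarmins (6 and 5), where the median (0.03) and the mean (-0.02) differed in sign. Over the alternatives those that fell ran from 6 to 13 for lysosome and autophagy, 2 to 7 for p53 targets and 1 to 4 for the interferon response. Among basal keratins, KRT14 went from 26149 ± 438 to 15707 ± 591 CPM (log2 -0.74 ± 0.06) while KRT15 rose by 1.13 ± 0.08. IL36RN, the antagonist of the IL-36 receptor, went from 160.5 ± 5.10 to 59.3 ± 2.64 CPM (log2 -1.44 ± 0.06).

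Lists of mitochondrial-encoded genes, endothelial cells, melanocytes and leukocytes were not tested. None of the 13 mitochondrial-encoded genes was in the table, and 3 members each of the other lists passed the filter, with highest mean levels of 24.7, 2.54 and 63.6 CPM. The endothelial marker VWF rose from 18.9 ± 1.21 to 30.6 ± 0.218 CPM at 32 ng/mL (log2 0.69 ± 0.10, adjusted p = 2.9e-04) and was higher at 64 ng/mL (0.40 ± 0.10, adjusted p = 0.00870). EGFL7, of the same list, moved the other way, from 9.32 ± 0.377 to 6.50 ± 0.676 CPM at 32 ng/mL (log2 -0.52 ± 0.12, adjusted p = 0.0133). That call was lost without untreated library 1 (0.0698) or 2 (0.0519) or the 32 ng/mL library 1 (0.0763) or 3 (0.0560). At 64 ng/mL EGFL7 was at -0.36 ± 0.13 (adjusted p = 0.0480), lost without any of the untreated or 64 ng/mL libraries or the 32 ng/mL library 3 (0.0516 to 0.142). With all libraries kept it was lost under DESeq2 (0.0906), RLE scaling (0.0510), no filter (0.0633) and thinning (0.0983). The replicate block (0.0528) and limma-trend on the authors' CPM (0.0558) lost it as well, as did a fit of only the groups compared (0.0594).

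**Figure D2:**
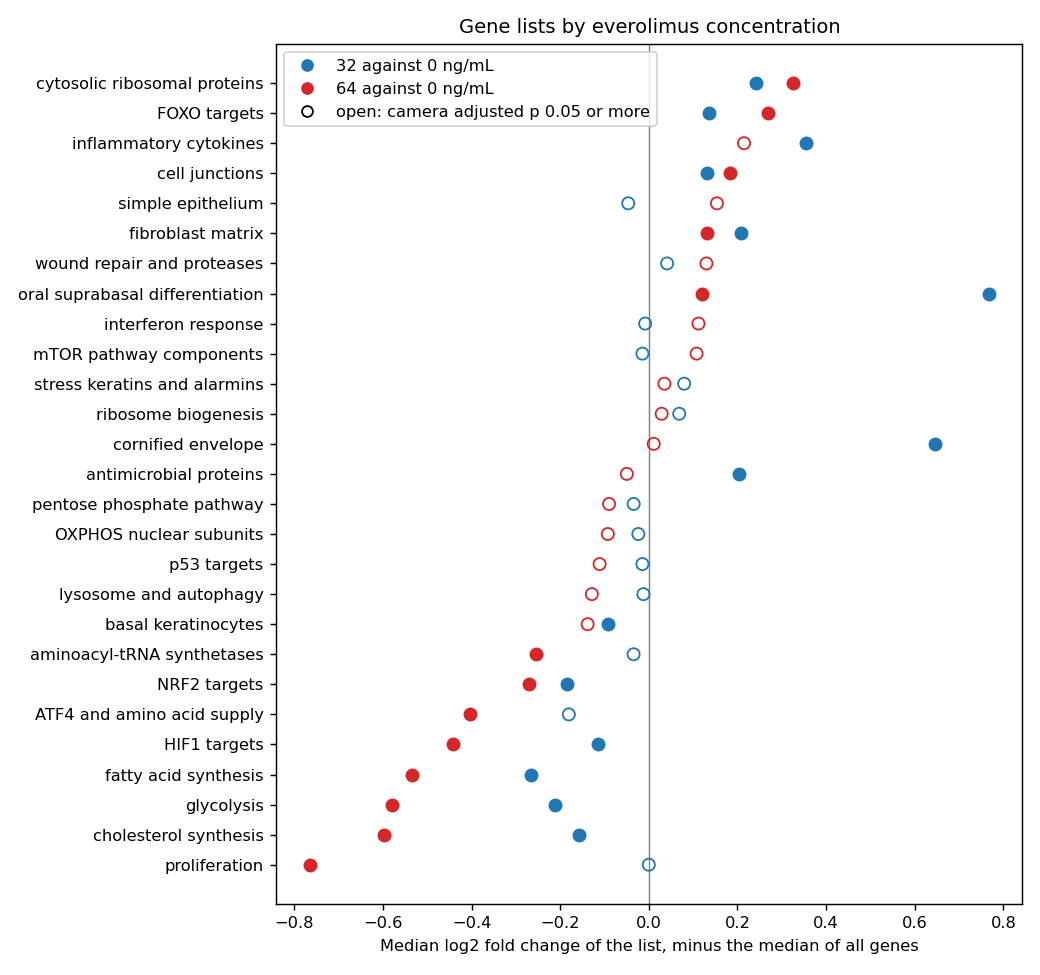
Median log2 fold change of each of the 27 tested gene lists minus the median of all genes (horizontal axis), at 32 ng/mL (blue) and 64 ng/mL (red) against untreated tissue, with open circles where the camera adjusted p was 0.05 or more. The cornified envelope list lies at 0.65 at 32 ng/mL and 0.01 at 64 ng/mL, and the proliferation list at 0.00 and -0.76.

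The third comparison set the concentrations against each other. Most genes of the cornified envelope and suprabasal lists were lower at 64 than at 32 ng/mL, though both calls were lost with an estimated correlation (adjusted p = 0.154 and 0.352). Among the exceptions, KRT76, KRT4 and KRT13 were higher, by 1.21 ± 0.10, 0.86 ± 0.09 and 0.27 ± 0.06. MUC16, a membrane mucin, was also higher. LOR went from 134 ± 11.6 to 45.3 ± 3.13 CPM (log2 -1.57 ± 0.08, edgeR adjusted p = 7.4e-09) and ARG1 from 15.1 ± 0.311 to 3.16 ± 0.923 (log2 -2.27 ± 0.16, adjusted p = 2.1e-07). MUC16 went from 12.6 ± 1.08 to 40.7 ± 4.39 CPM (log2 1.68 ± 0.10, adjusted p = 2.9e-08). In all, 2344 genes differed, 1134 higher and 1210 lower at 64 ng/mL, of which 84 and 194 by at least 2-fold. Groups did not overlap in 30.3% of all genes, where chance gives 10%. The 5 genes with the largest rise were MUC16, BMF, S100A7A, SECTM1 and DTX4 (1.36 to 1.68), and those with the largest fall were ARG1, LCE2A, PLA2G4D, LCE3E and C1orf68 (-2.27 to -2.05). The count of 2344 was 1490 without the 32 ng/mL library 3, 1547 with only the groups compared in the fit, and 4168 without the 64 ng/mL library 3 and the 32 ng/mL library 2.

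In the cornified envelope list, 25 of 35 were lower at 64 than at 32 ng/mL and 3 higher (26 and 4 adjusted over the list alone, median -0.54, adjusted p = 6.8e-12, and adjusted p = 0.154 with an estimated correlation). Without the 64 ng/mL library 3, 26 were lower and 6 higher. In the oral suprabasal differentiation list, 14 of 25 were lower and 3 higher (15 and 3 adjusted over the list alone, median -0.42, adjusted p = 2.6e-05; adjusted p = 0.352 with an estimated correlation). CRCT1 went from 735 ± 69.7 to 268 ± 19.4 CPM. In the inflammatory cytokines list, 10 of 26 were lower and 0 higher (10 and 0 adjusted over the list alone, median -0.34, adjusted p = 2.5e-04; adjusted p = 0.223 with an estimated correlation). IL36RN fell by 1.52 ± 0.06 and CXCL5 by 0.85 ± 0.10. In the 64 ng/mL library 3 the cytokine list lay 0.22 above the others of its group and the suprabasal list 0.31 above.

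The proliferation list was lower in 20 of 40 genes and higher in 1 (26 and 1 adjusted over the list alone, median -0.67, adjusted p = 1.9e-12, and adjusted p = 0.0189 with an estimated correlation). The count was 13 without the 32 ng/mL library 1. BIRC5 fell by 1.64 ± 0.23. The cholesterol synthesis list was lower in 20 of 25 and higher in 0 (20 and 0 adjusted over the list alone, median -0.42, adjusted p = 4.1e-12, and adjusted p = 0.00724 with an estimated correlation). MSMO1 fell by 1.14 ± 0.13. The HIF1 targets list was lower in 13 of 19 and higher in 0 (15 and 0 adjusted over the list alone, median -0.40, adjusted p = 4.2e-09, and adjusted p = 0.00733 with an estimated correlation). NDRG1 went from 1094 ± 37.5 to 681 ± 6.30 CPM. The glycolysis list was lower in 16 of 21 and higher in 0 (18 and 0 adjusted over the list alone, median -0.42, adjusted p = 5.4e-12; adjusted p = 0.133 with an estimated correlation). ALDOC fell by 1.22 ± 0.09. The ATF4 and amino acid supply list was lower in 15 of 29 and higher in 0 (18 and 0 adjusted over the list alone, median -0.32, adjusted p = 1.4e-05; adjusted p = 0.452 with an estimated correlation). The count was 7, 6 and 9 without the 32 ng/mL library 2, the 32 ng/mL library 3 and the 64 ng/mL library 2. The fatty acid synthesis list was lower in 8 of 15 and higher in 0 (12 and 1 adjusted over the list alone, median -0.34, adjusted p = 7.5e-05; adjusted p = 0.119 with an estimated correlation). The count was 4 without the 64 ng/mL library 2. The aminoacyl-tRNA synthetases list was lower in 9 of 20 and higher in 1 (11 and 2 adjusted over the list alone, median -0.21, adjusted p = 5.4e-04; adjusted p = 0.231 with an estimated correlation). The count was 5 and 4 without the 32 ng/mL library 2 and 3.

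The cytosolic ribosomal proteins list was higher in 6 of 77 genes and lower in 1 (6 and 1 adjusted over the list alone, median 0.08, adjusted p = 0.00218; adjusted p = 0.609 with an estimated correlation). RPL41 rose by 0.35 ± 0.06. Its call was lost without the 32 ng/mL library 1 (adjusted p = 0.127), and fry gave an adjusted p of 0.178. The count of 6 was 2 without the 32 ng/mL library 1 or 3, 19 without the 32 ng/mL library 2, 11 and 17 without the 64 ng/mL library 1 and 3, and 51 without the 64 ng/mL library 3 and the 32 ng/mL library 2 together. The other 16 lists were not called between the concentrations, with adjusted p from 0.0522 to 0.894. Antimicrobial proteins, lower in 7 of 14 and higher in 2 (7 and 2 adjusted over the list alone, adjusted p = 0.0609), were called without untreated library 1 (0.0472), the 32 ng/mL library 1 (0.0402) or 3 (0.0333) or the 64 ng/mL library 3 (0.0153). With all libraries kept they were called after thinning (0.0185), with limma-trend on the authors' CPM (0.0438), with the filter of 1 CPM (0.0495) and by fry (0.0341). NRF2 targets were called without the 32 ng/mL library 1 (0.0370), simple epithelium without the 32 ng/mL library 2 (0.0345) or 3 (0.0390), and stress keratins and alarmins without the 64 ng/mL library 3 (0.0179), and fry called all 3 with all libraries kept (0.000464, 0.00114 and 0.0341). For basal keratinocytes the median (-0.04) and the mean (0.04) differed in sign, and for ribosome biogenesis the median (-0.01) lay against the direction camera gave. Fibroblast matrix genes were higher in 6 of 29 and lower in 6 (6 and 6 adjusted over the list alone), with FN1 up by 1.34 ± 0.06.

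**Figure D3:**
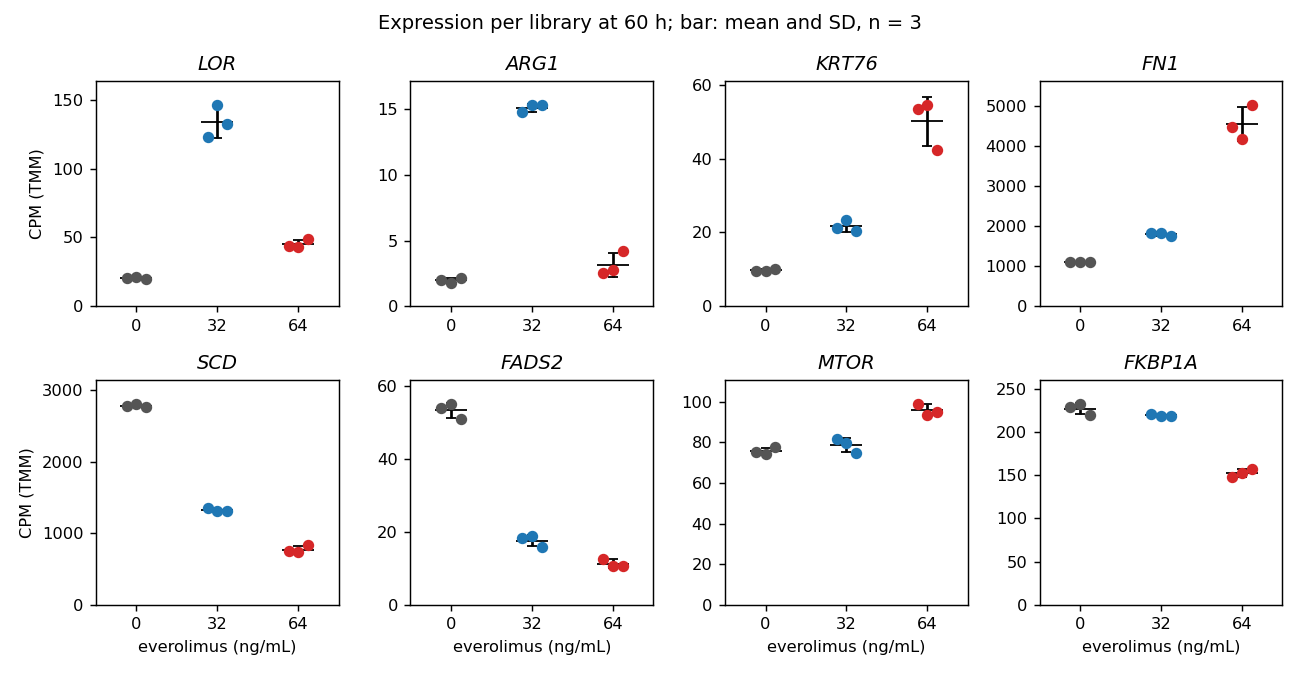
Expression of 8 genes in CPM (TMM-scaled, vertical axes from 0) at 0, 32 and 64 ng/mL everolimus, with 1 point per library and bars for mean and SD of 3 libraries. LOR and ARG1 are highest at 32 ng/mL (134 and 15.1 CPM), KRT76 and FN1 at 64 ng/mL (50.1 and 4563 CPM), and SCD and FADS2 are lowest at 64 ng/mL (769 and 11.3 CPM).

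The responses to both concentrations were then set side by side. Against untreated tissue, 476 genes were up and 405 down at both, of which 98 and 133 moved further at 64 than at 32 ng/mL. Another 60 were called in opposite directions, 45 of them up at 32 and down at 64 ng/mL. There were 751 genes up and 633 down that were called at 64 ng/mL and between the concentrations but not at 32 ng/mL. The log2 fold changes correlated across genes with r = 0.517, genes not being independent replicates, and simulated unchanged groups against the same controls gave a median of 0.472 (0.425 to 0.534 in 40 simulations). The covariance was 0.0792 against a simulated 0.0170, a difference of 0.0622. The same sign was seen in 69.8% of genes against a simulated 65.8%. Independent lists of these sizes would share 115 genes up and 75.8 down. Simulated unchanged groups shared 0 and 0, but no gene was changed in them, so they give no value for lists of these sizes. The 3 untreated libraries were too few to give each concentration its own controls, so the shared counts set against independent lists include what the shared controls add. Averaged over both concentrations against untreated tissue, 2972 genes were called, 1548 up and 1424 down, of which 103 and 110 changed at least 2-fold. With upper-quartile scaling the split was 1301 up (43.4%) and 1700 down. That count was 1807, 1819 and 1934 without untreated library 1, 2 and 3, and 4561 without the 64 ng/mL library 3 and the 32 ng/mL library 2. The correlation was 0.443 without the 32 ng/mL library 1, and 0.469 and 0.444 without the 64 ng/mL library 2 and 3.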

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

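The count of lower members among genes with whole counts and the thinning of libraries to 1 total were chosen after the results were seen.

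The cornified envelope list rose at 32 ng/mL, a camera call lost with an estimated correlation (adjusted p = 0.0673). It was lower at 64 than at 32 ng/mL, with 25 of 35 genes lower (camera adjusted p = 6.82e-12, and adjusted p = 0.154 with an estimated correlation). Lower depth at 64 ng/mL is argued against, since 25 genes were lower with every library thinned to the smallest total, and so is a single library, since the number ran from 21 without the 64 ng/mL library 2 to 26 without the 64 ng/mL library 3. For reads shared between near-identical genes, the 14 members with whole counts had a median of -0.45 (spread 0.148), which narrowly missed the bound set beforehand. The spread given with a median, here and below, is the genes' interquartile range divided by 2 and by the square root of their number. It takes genes as independent and does not measure the spread between libraries. Of those 14, 10 were lower at 64 than at 32 ng/mL and 8 had risen at 32, which argues against shared reads in them and leaves shared reads open for the other 21. An effect of concentration on late differentiation may account for the pattern and is a hypothesis only, found and tested on the same libraries.

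The oral suprabasal differentiation list showed the same change of direction between the concentrations (adjusted p = 2.64e-05; adjusted p = 0.352 with an estimated correlation). So did the inflammatory cytokines list (adjusted p = 0.000253, and adjusted p = 0.223 with an estimated correlation). The rise of each list at 32 ng/mL was also lost with an estimated correlation (camera adjusted p = 0.0673 for each). Among single genes, 276 were up at 32 ng/mL and lower at 64 than at 32, of which 187 were not called at 64 ng/mL against untreated. Another 87 were down at 32 ng/mL and higher at 64 than at 32, of which 69 were not called at 64 ng/mL. Both counts pick genes by their level at 32 ng/mL and compare them with the same libraries, which leans towards a return, and no value for unchanged genes was computed.

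The samples were also split in every other way. For 32 against 0 ng/mL the real split called 1346 genes and the highest of the other 9 called 0, for 64 against 0 it was 3928 against 0, and for 64 against 32 it was 2344 against 1. In each, 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. With the 6 treated libraries as 1 group against the 3 untreated, which pools the concentrations and so counts their difference as spread, the real split called 1122 genes. Of the 84 splits, 2 called as many, a share under 0.05. The other was the 3 libraries at 64 ng/mL against the rest, with 2583, which also follows the concentration labels. The splits take the libraries as independent, which the labels do not state. A difference between cultures that ran with concentration would give the same result and cannot be told apart here.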

How the results depend on the processing

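Thinning to 1 total and the fit without the 64 ng/mL library 3 and the 32 ng/mL library 2 (without both, below) were chosen after the data were seen. None of the named genes and lists called in the main analysis reversed direction, and those not called were not checked for it. Some lists not called had another direction under fry, such as inflammatory cytokines at 64 ng/mL (up by camera, down by fry). Under limma-trend on the authors' CPM, 1 called gene changed sign at 32 ng/mL and 1 between the concentrations. Upper-quartile scaling turned the majority from up to down at 32 (652 up, 708 down), at 64 (1752, 2145) and for the mean of both (1301, 1700). Of 9128 values of named genes under alternatives, 8709 stayed on their side of the threshold, 335 lost and 84 gained a call; of 1377 list values the numbers were 1299, 45 and 33. With 1 library left out, genes called ran from 723 to 2371 at 32 ng/mL, 2728 to 4337 at 64, 1490 to 3192 between the concentrations and 1807 to 3816 for their mean; lists called ran from 13 to 15, 12 to 13 and 11 to 13, and the correlation of responses from 0.443 to 0.547. Genes called without both were 3227, 5141, 4168 and 4561 and the correlation was 0.426. With only the groups compared, 2345, 3617 and 1547 genes were called. At an adjusted p under 0.01 the counts were 696, 2313, 1210 and 1689, and at 2-fold or more 179, 456, 278 and 213, fewer by construction. Camera with an estimated correlation called 0, 4 and 3 lists against 14, 13 and 11, and fry, which does not compare a list with other genes, 14, 19 and 20. Apart from those named, the cause was not tested.

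DESeq2 called 1387, 3692, 2308 and 2833 genes and limma-voom 1450, 3935, 2322 and 3105. Upper-quartile scaling gave 1360, 3897, 2358 and 3001, and thinning 1115, 3544, 2149 and 2589. Scaling moved the median of all genes by at most 0.032.

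The groups share replicate numbers. Correlations between libraries of different groups were taken on what remained of log2 CPM after each gene's group mean was subtracted. By this measure same-numbered libraries correlated at -0.09 to 0.14 over 9 pairs, 1 of them over 0.1, and other pairs at -0.17 to 0.16. No pairing was seen, but values this weak do not exclude it, and the labels do not say. With the replicate block, 1397, 3961, 2420 and 3049 genes and 13, 13 and 11 lists were called, and the correlation was 0.518. The HIF1 targets list at 32 ng/mL lost its call (adjusted p = 0.0867).

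In simulated data, 19.5% of the smallest changes at 32 ng/mL were recovered, so small changes were often missed.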

Other observations

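The tests of a fibroblast share, the tests of ribosomal protein genes at 32 ng/mL, the choice of the region on chromosome 1 and the values of single distant libraries below were chosen after the results were seen.

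The epidermal differentiation region of chromosome 1, taken between S100A10 and S100A1 (151982915 to 153632039, GRCh38, GENCODE release 29), held 55 tested genes, 29 of them in a fixed list and 28 with fractional counts. At 32 ng/mL 38 rose and 1 fell, so 69.1% rose against 5.66% of the 13921 tested genes that the tables list. At 64 ng/mL 25 rose and 7 fell. Between the concentrations 42 were lower at 64 than at 32 ng/mL and 3 higher, 76.4% lower against 8.69% of those 13921. C1orf68 of this region went from 1.13 ± 0.376 to 14.9 ± 0.301 and 3.57 ± 0.368 CPM at 0, 32 and 64 ng/mL.

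The cytosolic ribosomal protein genes had a median log2 change of 0.24 at 32 and 0.32 at 64 ng/mL. Length and GC content were those of each gene's longest annotated transcript, which need not be the one expressed (7686 bases for RPL37, 699 for RPL41). Genes matched on that length and on expression had a median of 0.0514 at 32 and -0.0683 at 64 ng/mL. The highest of 10000 matched lists gave 0.13 and 0.08. With GC content in place of length the medians were 0.0620 and 0.0497 and the highest values 0.16 and 0.24. The ribosomal protein medians lay above these. That argues against a bias by annotated length or GC content and leaves open one by those of the expressed transcripts. The 57 members with whole counts had medians of 0.24 (spread over genes 0.0045) at 32 and 0.31 (spread over genes 0.0083) at 64 ng/mL. That argues against reads shared with pseudogenes only where the reference used for counting held them, and its annotation is not given. Between libraries the spread was wider. The median of the whole list per library was 0.162, 0.333 and 0.226 at 32 ng/mL, and 0.351, 0.318 and 0.316 at 64 ng/mL. A coordinated rise of these transcripts may be biological, as a hypothesis found and tested on the same libraries.

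In the fibroblast matrix genes, led by FN1 and TAGLN, a larger share of fibroblast RNA is argued against as the cause of the size of the FN1 rise at 64 ng/mL, since the 10 most abundant other members had a median log2 change of 0.12 (spread 0.0214, 3 of 10 up) while FN1 was at 2.05 and COL1A1 at 0.01. As 9 of those 10 were positive, a small rise in the share of fibroblast RNA at 64 ng/mL could account for the small shift of the list and stays open. At 32 ng/mL the same 10 genes had a median of 0.25 (spread 0.018), with 10 of 10 positive and 6 up, so a larger share could account for part of the rise there too. An odd library is argued against, since leaving out any 1 library changed the folds of FN1 (3.94 to 4.32) and TAGLN (4.14 to 4.38) at 64 ng/mL by at most 1.05 times, and a change of these genes within a cell type was not tested.

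In the 64 ng/mL library 3, antimicrobial protein genes lay 0.28 above the others of the group and proliferation genes 0.15 above, beside the lists given with the comparison.

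The authors' CPM equalled the rounded expected counts times 1 factor per library, within 0.51 reads, for 25332 genes. The other 11 were C2, C3, C7, C9, F2, F3, F5, F8, F10, F12 and H19, all of them named by 1 letter and a number, of 16 such names in the table. After a shift by 2 columns, 8 of the 11 matched within 0.51 reads, and C2, F12 and H19 did not (17.2, 16.4 and 1486 reads). Of the 11, 7 were tested. The tests rest on the expected counts, and which of the 2 deposited tables is right for these genes was not tested.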
